A study of Mus musculus with 3 samples.

How the data were processed

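Single-cell RNA sequencing with the 10x Genomics 3' chemistry was run on dissociated brainstem from 3 mice. DIPG4423 is a murine diffuse midline glioma (DMG) line; 100000 cells of it were injected into the brain of B6(Cg)-Tyrc-2J/J mice, and brainstem was taken 3 weeks later from untreated animals. A pair of such libraries form the tumour group (tumour 1 and tumour 2), and the third library comes from brainstem without tumour (normal). Per the labels' protocols, mice were perfused with saline, the tissue was ground without an enzyme step being named, myelin was depleted with magnetic beads and red cells were lysed. The bead step can lower oligodendrocyte counts and the lysis step can lower erythroid counts in every library.

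The deposited files hold whole-number UMI counts per gene and barcode, with no normalization. They were made with Cell Ranger 6.1.2, per the file headers, on mm10, per the submitters' processing notes. The barcodes were already limited to called cells, with the lowest total in a library at 500 to 502 UMIs. Each library lists 32285 features with an identifier and a symbol. Gene positions come from GENCODE mouse release 21 (GRCm38, the assembly that mm10 names); 32235 identifiers matched and 50 did not.

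Barcodes were kept with at least 500 UMIs, at least 300 detected genes and at most 15% mitochondrial UMIs. Doublets were called per library with Scrublet (expected rate 8%) in scanpy 1.11.5 and removed. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes gave 30 principal components, and 15 nearest neighbours fed Leiden clustering (igraph 0.11.9) at resolution 1.0. No integration across libraries was applied, so a cluster can reflect a library. Clusters were named from 18 marker lists that were fixed before the data were examined, as were the tests, the 28 gene lists, the rule for named genes and the alternatives except those listed below as added. The naming score was set after the clusters had been seen. It is the mean log2 level of a list's markers in a cluster over the mean of all clusters, with 0.05 added, and had to reach 1 with at least 3 markers detected in 10% of cells. A cluster stayed unnamed where another list had more markers among its top 10 genes, or where 3 times its median UMI count lay below its libraries' median and no own marker was among those genes. Also after seeing the clusters, T and NK cell markers were merged, border macrophage markers named the macrophage class, and a cluster led by Elane, Mpo, Prtn3 and Ctsg was left unnamed as granulocyte precursors. No cluster was named ependymal or, at this resolution, monocyte. Names are rebuilt from markers, so classes are called microglia-like and so on.

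UMI counts were summed per library over all kept cells and over each class with at least 20 cells in all 3 libraries. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, Benjamini-Hochberg threshold 0.05). With 2 libraries against 1, the fit has 1 residual degree of freedom, which comes from the tumour pair: the lone normal library is assumed to vary like the tumour libraries. An exact permutation of 2 against 1 cannot give a p under 1 in 3. Beyond their titles nothing states how the samples relate, so the edgeR p-values measure the spread between these libraries. In astrocyte, B, choroid plexus, neuron and T or NK-like cells the prior degrees of freedom of the fit were infinite. The 1 residual degree of freedom carried no weight in those classes. Very small p-values there rest on a spread pooled over genes, not on that of the gene itself. The test was tried on simulated counts with 200 changed genes, some of which the low-count filter removed. For the whole library (20470 genes) it recovered 1.05% of 95 genes changed 2-fold and 28.1% of 96 genes changed 4-fold, with 1 false among 29 calls. For the microglia class (15029 genes) it recovered 9.28% of 97 and 61.1% of 95, with 3 false among 70 calls. All 3 simulated libraries shared the same dispersion, and the lone normal library had no effect of its own. The false calls in the real data are therefore not measured by it.

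Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, over 27 lists. The sex-linked list served as a check of samples. Camera p-values at the preset correlation set the genes of a list against all other genes. Genes are the unit there, so a very small p is not evidence from replicate libraries. Members adjusted over the list alone were counted too. A pair of further list tests, camera with an estimated correlation and one-directional fry, served as alternatives. The estimated correlation and its test rest on the 1 residual degree of freedom. That camera test could hardly pass here, so its large p-values speak neither for nor against a list. Cell numbers per class were tested with edgeR on counts of cells. Shares have exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only. A fold against a group with 0 counts is a lower bound computed against 3 counts over that group, and ratios on 1 to 3 counts carry a counting interval. To compare cycling cells across depths, each cell was thinned to 1000 UMIs and shallower cells were left out.

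Free RNA in droplets was bounded per class and library. Indicator genes of other cell types gave the share of the whole-library level found in the class, and a called gene counted as above free RNA where its level exceeded 2 times what the highest such share allowed. The indicators were genes of progenitors, microglia, neutrophils and neurons, so no share was measured for RNA of other cell types. This guard was added after the data were seen.

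The named genes are the 10 with the highest and the 10 with the lowest log2 fold change in the whole library and in microglia-like cells (5 and 5 in other classes) among genes past the threshold. They needed a mean CPM (the deposited counts scaled to a common library total) of 50 in either group and the same direction in both tumour mice. CPM carry no TMM factor, whereas log2 changes do, so CPM ratios and log2 changes can differ. Predicted Gm and Rik genes, mitochondrial, ribosomal, haemoglobin and immunoglobulin genes were left out. From each list, 2 to 4 members with the smallest adjusted p are named. Pdgfra, Olig2, Mki67, Cd274, Trp53 and Cdkn2a are always given. Some genes that this rule selects are not reported here. Text names fewer where a class is described in short, and genes outside the rule are named as chosen after their values were seen.

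Alternatives fixed beforehand were no cell filter, a stricter filter (1000 genes, 5% mitochondrial), doublets kept, resolutions 0.5 and 2.0, RLE scaling, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, each tumour library left out, other list tests, and other depths and genes for the cycling share. Alternatives added after seeing the data were scaling by library size alone, sums thinned to the depth of the shallowest library, the free RNA guard, the whole library without marrow-type clusters, endothelial-like cells with a low share of mural UMIs, and the difference between microglia-like and endothelial-like cells for 2 lists. Thinning was first done with edgeR's thinCounts. Its draws varied 2.23 to 26.6 times as much as a binomial draw would in the 11 comparisons, so binomial thinning, at 0.965 to 1.02 times, was added. Both outcomes are given, except that some counts within 1.5 times of the reported count are left out. Batch was not examined, as the labels name none. Mural, oligodendrocyte, erythroid, fibroblast and glial progenitor-like cells had under 20 cells in at least 1 library and have values without a gene test. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.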

Results

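Single-cell transcriptomes were collected from brainstem of 2 mice carrying a diffuse midline glioma (DMG) graft and from 1 normal brainstem. Diffuse midline glioma is a childhood tumour of the brainstem and midline. The graft was the murine line DIPG4423, taken 3 weeks after injection of 100000 cells into immunocompetent mice, and the series concerns such syngeneic models. The comparison of tumour-bearing with normal brainstem asks which cells and transcripts differ between them. Tumour 1 held 12118 barcodes and 151906460 UMIs, tumour 2 held 10728 and 157114723, and the normal library 4354 and 15035292. Median UMIs per barcode were 7486, 9978 and 2493.5, and median genes 2804.5, 3091 and 1107.5. Barcodes over the mitochondrial limit made up 9.71%, 9.57% and 26.3%. After filtering, 10562, 9410 and 3076 cells remained with medians of 8777.5, 11294.5 and 2394 UMIs. The normal group has no replicate, so its values carry no spread between animals.

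Sex-linked genes served as a check of samples. Xist, the RNA that silences an X chromosome in female cells, stood at 1072 and 1059 CPM in glial progenitor-like cells of tumour 1 and tumour 2. Summed CPM of the Y genes Ddx3y, Eif2s3y, Kdm5d and Uty was 2.03 and 4.50 there. In microglia-like cells Xist stood at 20.3, 21.2 and 0 CPM in tumour 1, tumour 2 and normal, and the Y genes at 201, 181 and 321. The progenitor-like cells and the host cells of the same libraries therefore differed in sex-linked expression.

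**Figure D1:**
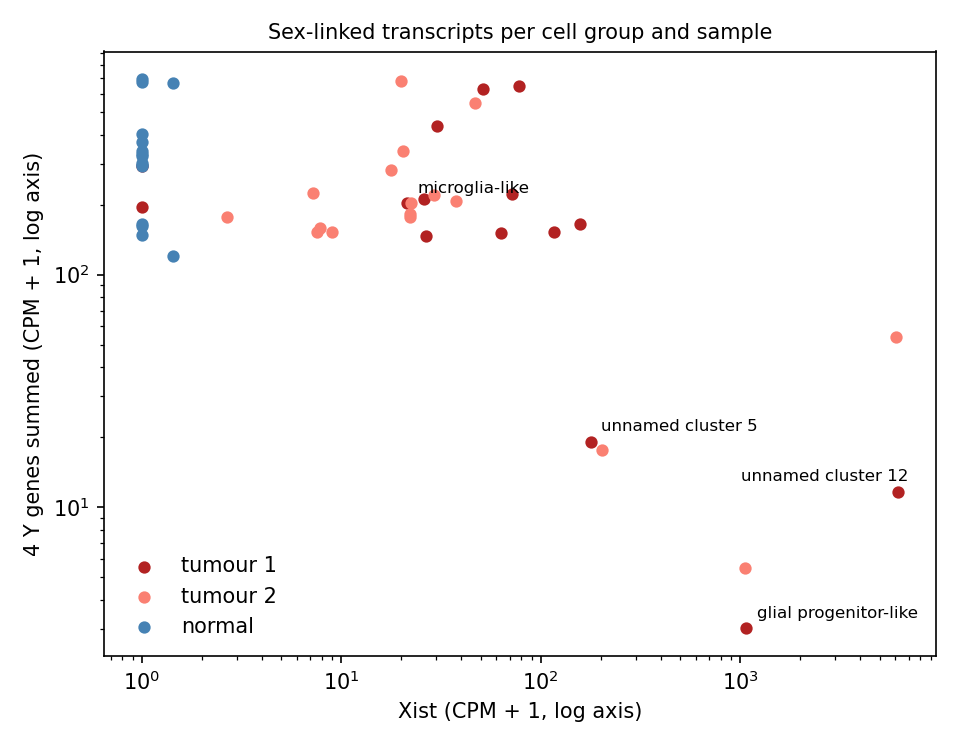
Xist CPM (x axis, plus 1, log scale) against the summed CPM of 4 Y-linked genes (y axis, plus 1, log scale) for each cell group, with 1 point per group and library. Glial progenitor-like cells lie at 1072 and 1059 CPM of Xist, and microglia-like cells at 20.3, 21.2 and 0.

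Glial progenitor-like cells, which carry Pdgfra, Olig1 and Sox10, made up 41.5% of tumour 1 (4378 cells; exact 95% interval 40.5 to 42.4%) and 22.4% of tumour 2 (2111 cells; 21.6 to 23.3%). In the normal library 2 cells had that name, 0.065% (0.0079 to 0.235%). Microglia-like cells made up 30.1%, 35.7% and 23.8% in tumour 1, tumour 2 and normal. Macrophage-like cells made up 5.98%, 14.9% and 0.910%, and mural-like cells 0.606%, 1.57% and 0.130%. Neuron-like cells made up 1.61%, 3.24% and 19.8%, neutrophil-like cells 3.06%, 5.26% and 17.0%, and B-like cells 0.189%, 1.03% and 7.38%. With the stricter cell filter progenitor-like cells made up 23.6%, 14.6% and 0.528% (7 cells), microglia-like cells 50.9%, 43.8% and 27.0%, macrophage-like cells 8.59%, 13.2% and 0.377%, neuron-like cells 3.12%, 3.02% and 33.6%, and B-like cells 0.167%, 1.33% and 1.28%. At resolution 2.0 neutrophil-like cells 1.39%, 2.20% and 16.9%, since a cluster with 176, 288 and 1 of these cells lost the name. Oligodendrocyte-like cells, a type that myelin removal beads deplete, made up 0.0663%, 0.0744% and 2.70%, and erythroid-like cells, which lysis removes, 0.0568%, 0.117% and 0.813%. The stricter filter left 1, 0 and 9 oligodendrocyte-like cells, and without a cell filter erythroid-like cells made up 0.196%, 0.630% and 2.64%. Of the tested classes, glial progenitor-like cells rose (log2 change 8.91, SE 2.16, adjusted p = 0.0125, edgeR) and oligodendrocyte-like cells fell (-5.23, SE 1.38, adjusted p = 0.0126). Macrophage-like cells (3.52, adjusted p = 0.109), B-like cells (-3.60, adjusted p = 0.0667) and neuron-like cells (-3.03, adjusted p = 0.0913) did not pass. With doublets kept, progenitor-like (9.92) and oligodendrocyte-like cells (-5.17) did not pass either (adjusted p = 0.103 for both).

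The remaining classes were smaller. Astrocyte-like cells made up 4.18%, 1.29% and 6.34% of tumour 1, tumour 2 and normal, endothelial-like cells 0.701%, 2.31% and 4.65%, and T or NK-like cells 0.776%, 1.93% and 1.24%. Choroid plexus-like cells made up 0.227%, 0.776% and 0.975%, and fibroblast-like cells 0.0852%, 0.319% and 1.27%. With that stricter filter astrocyte-like cells made up 2.34%, 0.672% and 1.28%, T or NK-like cells 1.28%, 2.34% and 0.754%, choroid plexus-like cells 0.272%, 0.458% and 0.0754%, endothelial-like cells 0.439%, 1.10% and 1.28%, and fibroblast-like cells 0.815%, 1.27% and 0.377%. Without a cell filter the normal library had 12.6% astrocyte-like and 1.71% choroid plexus-like cells, and tumour 1 had 0.145% fibroblast-like cells; with doublets kept, astrocyte-like cells made up 9.91% of the normal library. Dendritic-like cells made up 0.369%, 4.09% and 1.37%; their log2 change of 0.71 became -1.88 without tumour 2 and 1.58 without tumour 1, and their share in the normal library was 0.260% at resolution 2.0. Unnamed clusters held 10.5%, 5.01% and 11.7% of cells. Among them, a cluster led by Elane, Mpo, Prtn3 and Ctsg, genes of granulocyte precursors in bone marrow, held 0.104%, 0.415% and 7.77%, and its naming rule was set after it was seen. Unnamed cluster 5, led by Gap43 and Fabp7, held 6.43%, 3.25% and 0.553%, and unnamed cluster 12, led by Tsix and Xist, held 2.76%, 1.12% and 0%. The fourth, with low UMI counts, held 1.21%, 0.223% and 3.35%.

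**Figure D2:**
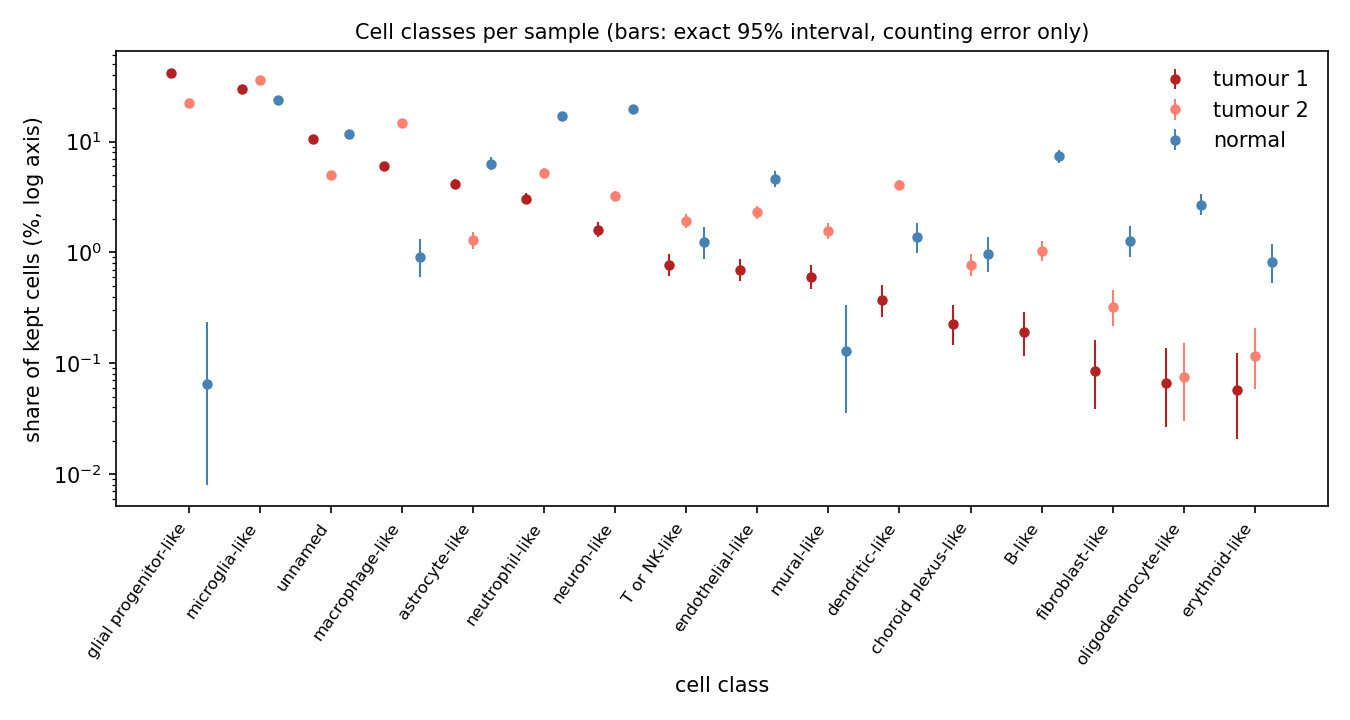
Share of kept cells in percent (log axis) for each cell class and library, with exact 95% intervals that cover counting error only. Glial progenitor-like cells stand at 41.5% and 22.4% in the tumour libraries and 0.065% in the normal library.

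Summed over all kept cells, 12 of 13 oligodendrocyte progenitor genes were higher in tumour-bearing than in normal brainstem, and 9 of 12 neuronal genes and 3 of 5 haemoglobin genes were lower. As lists, these 3 had adjusted p = 0.853 with an estimated correlation and passed only with the preset one. Pdgfra, the receptor that marks oligodendrocyte progenitors (chromosome 5, 75152292 to 75198215, GRCm38), stood at 675 ± 257 CPM (SD, n = 2) in tumour and 7.07 in normal (log2 change 7.12, SE 0.594, adjusted p = 0.00875, edgeR). Olig2, a transcription factor of that lineage (chromosome 16, 91225457 to 91228677), stood at 168 ± 70.5 CPM (SD, n = 2) against 6.53 (log2 change 5.23, adjusted p = 0.0106). Cdkn2a, a cell cycle inhibitor gene (chromosome 4, 89274471 to 89294653), stood at 328 and 223 CPM in tumour 1 and tumour 2 and 0.091 in normal, a ratio of 3026 with a counting interval of 543 to 119514 (adjusted p = 0.00832). Prg2, the major basic protein of eosinophil granules (chromosome 2, 84980461 to 84983632), fell from 1127 counts in normal to 3 over both tumour libraries, a ratio of 9763 with a counting interval of 3332 to 47413 (adjusted p = 0.00832). In all, 2638 genes rose and 1692 fell among 20470 tested. TMM scaling placed the median log2 change of all genes at 0.14 and scaling by library size alone at -0.42, under which 1671 rose and 3765 fell. Sums thinned to equal depth gave 2394 and 1926 after a binomial draw, and 392 and 255 with thinCounts, whose draws spread more widely.

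Other genes that rose in the whole library included Pnlip, a pancreatic lipase, at 149 and 91.3 CPM against 0 (at least 442-fold), Sox10 (log2 change 8.51), Bricd5 (9.90), Rlbp1 (8.82) and Susd5 (8.47). Ratios on few normal counts were 333 for Gpnmb (counting interval 92.3 to 2754; 169 without tumour 2) and 975 for Otos (175 to 38523; 639 without tumour 1). Genes that fell included Mcpt8 (-9.84) and Prss34 (-8.65), proteases of basophils and mast cells, Bglap (-9.48), the bone protein osteocalcin, and Vpreb3 (-7.09), a gene of B cell precursors. The granule genes Fcnb (-8.02), Mpo (-6.82), Elane (-6.76) and Ltf (-6.74) and the platelet gene Ppbp (-7.02) fell as well. Single tumour libraries moved some of these: without tumour 2 the change was -9.79 for Vpreb3 and -8.31 for Elane, and without tumour 1 it was -10.63 for Bglap. Mcpt8 stood at 0.014 and 0.082 CPM in tumour 1 and tumour 2 against 67.7 in normal, and Prss34 at 0 and 0.239 against 73.7. Mki67, a proliferation marker, gave 272 ± 12.2 CPM (SD, n = 2) against 252 (log2 change 0.67, adjusted p = 0.179). Trp53 gave 73.5 ± 3.69 against 53.2 (1.02, adjusted p = 0.0540), and Cd274, which encodes PD-L1, 5.88 ± 3.31 against 6.07 (0.54, adjusted p = 0.611); these 3 did not pass. The log2 changes include TMM factors of 0.921, 0.840 and 1.29 in tumour 1, tumour 2 and normal, and the CPM do not. Cd274 therefore differs in direction between the 2 scales. Without neutrophil-like, B-like, erythroid-like and precursor clusters, left out after their genes had been seen, 3740 genes rose and 2191 fell.

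The list of oligodendrocyte progenitor genes had 12 of 13 members higher and 0 lower in the whole library (12 higher adjusted over the list alone; median log2 change 5.75, camera adjusted p = 1.24e-21), among them C1ql1 (7.51) and Cspg4 (5.75). Of 19 genes of disease-associated microglia, 9 rose and 0 fell (15 higher adjusted over the list alone; median 2.69, adjusted p = 3.25e-06), including Fabp5 (3.38) and Spp1 (4.10). Of 15 dissociation stress genes 9 rose, including Egr1 (4.59) and Socs3 (3.75), and 0 fell (12 higher and 1 lower adjusted over the list alone; median 2.35, adjusted p = 3.25e-06). Of 18 chemokines and cytokines 5 rose, including Ccl2 (4.51) and Ccl12 (3.97), and 0 fell (8 adjusted over the list alone; median 2.06, adjusted p = 0.00126). Neuronal genes fell in 9 of 12 cases, with Snap25 at 8.47 ± 2.11 CPM (SD, n = 2) against 165, and 1 rose (10 lower and 1 higher adjusted over the list alone; median -3.61, adjusted p = 3.68e-09). Haemoglobin genes fell in 3 of 5 cases and 0 rose (5 lower adjusted over the list alone; median -2.44, adjusted p = 0.000563), including Hbb-bt (-3.64). Of 12 myelin genes 5 fell, including Mog (-4.62) and Mobp (-3.35), and 2 rose, including Ugt8a (3.19) (6 and 2 adjusted over the list alone; median -1.12, adjusted p = 0.0168). Without tumour 1, Mog changed by -5.28. Each of these 7 lists had adjusted p = 0.853 with an estimated correlation.

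Hypoxia genes of the whole library had 8 of 13 higher, including Adm (3.61), and Ndrg1 lower (-2.41) (9 and 2 adjusted over the list alone; median 1.75, camera adjusted p = 0.0168). Angiogenic endothelial genes had 3 of 12 higher and 0 lower, including Angpt2 (3.61; chromosome 8, 18690263 to 18741562) (3 adjusted over the list alone; median 1.58, adjusted p = 0.0327), whereas blood-brain barrier genes had 3 of 12 lower, including Slco1a4 (-3.81), and Bsg higher (1.53) (4 and 1 adjusted over the list alone; median -0.70, adjusted p = 0.045). The p53 target list had 5 of 14 higher, including Phlda3 (4.70), and Trp53inp1 lower (-1.62) (the same counts adjusted over the list alone; median 0.96, adjusted p = 0.0327). The list of polycomb genes and cell cycle inhibitors had Cdkn2a, Cdkn2b (3.19) and Cdkn2c (2.77) higher of 8 and 0 lower (4 adjusted over the list alone; median 0.72, adjusted p = 0.00217), and the PDGF list Pdgfra and Pdgfa (2.12) of 6 with 0 lower (2 adjusted over the list alone; median 0.94, adjusted p = 0.039). Cholesterol synthesis genes had 5 of 14 higher and 0 lower, including Fdps (2.40) (6 adjusted over the list alone; median 0.91, adjusted p = 0.019), and G2 and M phase genes 3 of 15 higher and 0 lower, including Cenpf (2.16) (8 adjusted over the list alone; median 0.89, adjusted p = 0.0327). Interferon response genes had Ifit1 (-2.26) and Rsad2 (-1.59) lower and Ifit2 (1.99) higher of 19 (the same counts adjusted over the list alone; median -1.13, adjusted p = 0.0168). Of 8 mitochondrial genes 0 passed by edgeR, and 0 adjusted over the list alone, although the list did (median 1.11, adjusted p = 0.0309). Without tumour 2, Angpt2 changed by 2.87 and Slco1a4 by -5.59. These lists had adjusted p = 0.853 to 0.878 with an estimated correlation.

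The other 10 lists did not pass in the whole library. Whole-library changes mix shares of cell classes with levels within cells, so a list name does not tell which cells changed. Extracellular matrix genes moved both ways, with Col1a2 (-5.29), Col1a1 (-4.87) and Col3a1 (-3.16) lower and 4 of 12 higher, including Tnc (6.01) (8 higher and 3 lower adjusted over the list alone; median 1.19, camera adjusted p = 0.713). Mesenchymal glioma genes had 4 of 14 higher, including Timp1 (4.15), and 5 lower, including Anxa1 (-4.43), with a median of -0.16 and a mean of 0.35 (adjusted p = 0.86). Reactive astrocyte genes had 3 of 12 higher, including Serpina3n (5.83), and 2 lower, including Lcn2 (-5.01) (median 0.14, adjusted p = 0.979). Lcn2 was also a leading gene of a neutrophil-like cluster with 38, 33 and 397 cells in tumour 1, tumour 2 and normal. Astrocyte genes had 5 of 13 lower, including Aqp4 (-2.78), and Aldoc higher (1.63) (median -0.35, adjusted p = 0.127). Checkpoint ligands and suppressive factors had 4 of 15 higher, including Cd276 (3.48) and Arg1 (4.30), and 0 lower (median 0.65, adjusted p = 0.0741). In these last 4 lists the counts adjusted over the list alone were the same. The T cell list had Nkg7 lower (-3.59) of 13 (0 adjusted over the list alone; median -1.06, adjusted p = 0.144), the MHC class I list Psme2 higher (1.31) of 12 (0 adjusted over the list alone; median 0.22, adjusted p = 0.813), and the S phase list 2 of 15 higher, Chaf1b and Ung (0 adjusted over the list alone; median 0.44, or -0.12 with library size alone, adjusted p = 0.569). Of 7 MHC class II genes 0 passed, with a median of 2.26 that was -0.06 without tumour 2 (0 adjusted over the list alone; adjusted p = 0.206), and of 13 homeostatic microglia genes 0 passed (0 adjusted over the list alone; median 0.03, adjusted p = 0.813). Among the called genes of these lists, Col1a2 changed by -5.95, Col1a1 by -5.71 and Anxa1 by -5.18 without tumour 2, and Aqp4 by -3.42 and Arg1 by 3.18 without tumour 1. At an unadjusted p under 0.05, edgeR counted 7738 genes in the whole library.

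Glial progenitor-like cells were compared between the tumour libraries as values, since 1 against 1 leaves no test. A cluster led by Pou3f1, Lhfpl3 and C1ql1 held 56.9% of the class in tumour 1 and 41.8% in tumour 2. A cluster led by Prss35, Vegfa and Car9, of which Vegfa and Car9 are hypoxia genes, held 17.2% and 24.4%, and a pair of clusters led by cell cycle genes held 11.9% and 12.4% (Exo1, Clspn) and 11.9% and 14.5% (Cenpf, Aspm). A cluster led by Fmod and Col6a1 held 2.12% and 6.87%. Pdgfra stood at 1174 and 1055 CPM in the class. The class I chain B2m stood at 202 and 216 CPM, beside 1759 and 2863 in microglia-like cells of the same libraries, H2-K1 at 61.5 and 62.5, and Cd274 at 0.625 and 0.591.

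Cycling cells were counted as those with a UMI of Mki67 or Top2a after thinning every cell to 1000 UMIs. Among glial progenitor-like cells 19.7% (exact 95% interval 18.5 to 20.9%) were cycling in tumour 1 and 24.9% (524 of 2108, upper bound 26.8%) in tumour 2. Among microglia-like cells 9.21% (8.20 to 10.3%), 7.35% (6.48 to 8.29%) and 0.521% (0.108 to 1.51%) were cycling in tumour 1, tumour 2 and normal. Neuron-like cells, which do not divide, gave a background of 3.01%, 3.53% and 0.936%, with median depths of 2766, 2481 and 3232.5 UMIs beside 4158, 8336 and 1883 in the microglia-like cells used. Macrophage-like cells gave 14.6%, 6.79% and 4.35% (1 of 23), neutrophil-like cells 5.88%, 4.54% and 14.2%, and endothelial-like cells 1.69% (1 of 59), 9.42% and 0 of 141. That 0 allows up to 2.13% of cells with such a UMI at this depth (3 counts of the total; 2.58% by the exact interval) and sets no limit on cells that express the genes. Thinned to 2000 UMIs, neutrophil-like cells gave 15.2%, 6.79% and 73 of 406. Thinning left out 142, 51 and 155 microglia-like cells that were too shallow. Unthinned, the shares were 53.4% and 60.7% in progenitor-like cells and 20.0%, 20.2% and 1.78% in microglia-like cells, and 29.7%, 39.6% and 1.40% (2 of 143) in endothelial-like cells.

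**Figure D3:**
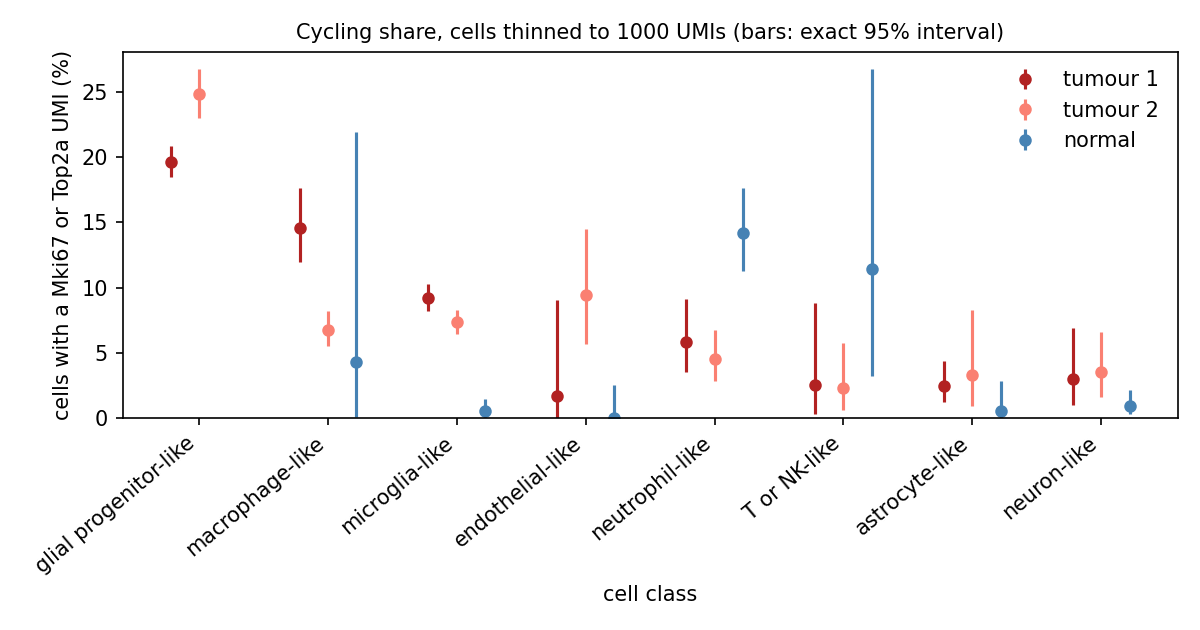
Percent of cells with a UMI of Mki67 or Top2a after thinning to 1000 UMIs, for 8 cell classes and 3 libraries, with exact 95% intervals. Microglia-like cells stand at 9.21% and 7.35% in tumour and 0.521% in normal, and neuron-like cells, a background, at 3.01%, 3.53% and 0.936%.

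In microglia-like cells of tumour-bearing brainstem 16 of 19 genes of disease-associated microglia and all 15 G2 and M phase and 15 S phase genes were higher, and 5 of 13 homeostatic genes were lower. As lists these had adjusted p = 0.70 to 0.72 with an estimated correlation and passed only with the preset one. Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), stood at 688 ± 25.8 CPM (SD, n = 2) against 64.5 in normal (log2 change 3.98, SE 0.345, adjusted p = 0.000648, edgeR). Hmox1, a haem-degrading enzyme, stood at 2631 and 1488 CPM against 21.3 (7.14, SE 0.576, adjusted p = 0.000434). P2ry12, a purine receptor of resting microglia (chromosome 3, 59216272 to 59262871), stood at 693 ± 48.8 CPM (SD, n = 2) against 2979 (-1.54, adjusted p = 0.00732). In all, 2198 genes rose and 1099 fell among 15029 tested, and 1921 and 930 of them lay above what free RNA could give. TMM scaling placed the median log2 change at 0.11 and library size alone at -0.45, under which 1319 rose and 3616 fell. Different clusters held most of the class: one led by Gpr34 and P2ry12 held 3.05%, 24.4% and 91.7% in tumour 1, tumour 2 and normal, one led by Lag3, Cst7 and Ccl12 held 23.8% and 42.6% in the tumour libraries, and one led by Hmox1 and Spp1 held 17.6% and 20.5%. A further one, led by Bmf, Tlr7 and Havcr2 among named genes, held 46.9%, 3.72% and 2.87%. With sums thinned to equal depth 1850 genes rose and 1343 fell after a binomial draw, and 0 and 0 after thinCounts, whose draws spread more widely (530 at an unadjusted p under 0.05).

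Other genes that rose in microglia-like cells were Cst7 (log2 change 5.82), Fabp5 (5.75), Igf1 (4.45) and Mki67 (4.43), with Gpnmb at a ratio of 119 (counting interval 21.3 to 4692; 64.5 without tumour 2) and Wfdc17 at 92.0 (16.5 to 3634). Ier3, Fn1 (4.77) and Lgals1 (4.56) rose too, at levels that free RNA could give. Cdr1os (-6.32), Snap25 (-4.85), the cytokine receptor Il7r (-3.20) and AC160336.1 (-2.79) fell, as did Ngp (-5.76), S100a9 (-4.23), S100a8 (-3.57), Snhg11 (-3.58), Rian (-3.25) and Meg3 (-2.78). The last 6 of these, genes of neutrophils and neurons, lay within the level of free RNA in the normal library. Snap25 is itself 1 of the 5 neuron genes that set this level, so free RNA is not excluded for it. Cdr1os also fell in endothelial-like, astrocyte-like (-5.2), macrophage-like (-5.9) and neutrophil-like cells (-5.2), and free RNA is not excluded for it either. Cst7 changed by 5.19 without tumour 2, and Ier3 by 4.66 and Fn1 by 3.69 without tumour 1. Of 19 disease-associated genes 16 rose and 0 fell (17 adjusted over the list alone; median 2.92, camera adjusted p = 8.8e-25), and 16 lay above free RNA. Of 13 homeostatic genes 5 fell, including Gpr34 (-1.60) and P2ry13 (-1.34), and 0 rose (8 adjusted over the list alone; median -0.86, adjusted p = 1.06e-05). All 15 G2 and M phase genes rose, with Top2a at 3.53 (15 adjusted over the list alone; median 3.53, adjusted p = 6.02e-19), and 10 of them lay above free RNA. All 15 S phase genes rose as well (15 adjusted over the list alone; median 2.38, or 1.93 with members at their bound, adjusted p = 9.11e-10). For these 4 lists the adjusted p = 0.70 to 0.72 with an estimated correlation.

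Chemokine and cytokine genes rose in 8 of 16 cases in microglia-like cells and 0 fell, with Ccl12 (3.77), Ccl2 (2.98) and Tnf (3.45) higher (9 adjusted over the list alone; median 2.23, or 1.71 with members at their bound, camera adjusted p = 0.000203). Interferon response genes rose in 6 of 19 cases and 0 fell, including Ifi27l2a (2.09), Ifitm3 (2.49) and Bst2 (1.90) (6 adjusted over the list alone; median 1.48, adjusted p = 0.013). MHC class I genes rose in 5 of 12 cases and 0 fell, including Psmb8 (1.82) and H2-D1 (1.67) (6 adjusted over the list alone; median 1.06, adjusted p = 0.00407), and MHC class II genes in 3 of 7 and 0 fell, of which 1 lay above free RNA (4 adjusted over the list alone; median 1.30, adjusted p = 0.0314). Hypoxia genes rose in 5 of 13 cases and 0 fell, including Pgk1 (2.47) and Ldha (2.16) (5 higher and 1 lower adjusted over the list alone; median 0.93, adjusted p = 0.0482). Dissociation stress genes rose in 7 of 15 cases and 0 fell (7 adjusted over the list alone; median 1.39, adjusted p = 0.000183). Checkpoint ligands had 3 of 15 lower, including Entpd1 (-1.28), and 0 higher (3 adjusted over the list alone; median 0.14, adjusted p = 0.293). Without tumour 1 the change of Tnf was 2.70, and without tumour 2 that of Ifitm3 was 1.84 and that of H2-D1 1.02. Genes of other cell types moved too: 7 of 13 oligodendrocyte progenitor genes rose, 0 of them above free RNA (8 adjusted over the list alone; median 3.77, adjusted p = 0.000211), and 7 of 9 neuronal genes fell, 5 of them above free RNA (8 adjusted over the list alone; median -3.47, adjusted p = 1.56e-10). Snap25, Syt1 and Nrxn3 of the neuronal list are among the 5 neuron genes that set the free RNA level. Those 5 ranged from 9.52 to 39.9% of the library level in normal microglia-like cells. The bound therefore cannot separate these falls from free RNA. With an estimated correlation the adjusted p = 0.70 to 0.723 for the lists that passed.

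In endothelial-like cells of tumour-bearing brainstem 9 of 12 angiogenic, 11 of 12 matrix and all 13 mesenchymal genes tested were higher, and 10 of 12 barrier and 13 of 19 interferon genes were lower. As lists these 5 had adjusted p = 0.626 with an estimated correlation and passed only with the preset one. Angpt2, a secreted ligand of sprouting vessels, stood at 783 ± 84.8 CPM (SD, n = 2) against 16.2 (log2 change 5.83, SE 0.356, adjusted p = 3.82e-05, edgeR). Slco1a4, an organic anion transporter of the barrier (chromosome 6, 141805440 to 141856199), stood at 478 ± 51.0 CPM (SD, n = 2) against 4108 (-2.86, SE 0.210, adjusted p = 4.90e-05). Ifit1, an interferon-induced RNA-binding protein (chromosome 19, 34640871 to 34650009), stood at 1.26 and 10.1 CPM against 269 (-4.89, SE 0.446, adjusted p = 8.23e-05), and its change without tumour 2, on few counts, was -7.39. The monocyte chemokine gene Ccl2 (chromosome 11, 82035571 to 82037453) stood at 882 and 409 CPM against 0, at least 199-fold higher, or 126-fold without tumour 1. In all, 2182 genes rose and 1593 fell among 11372 tested, with 1655 and 1583 above free RNA. Sums thinned to equal depth gave 2124 and 1627 after a binomial draw and 674 and 379 with thinCounts. The class held 74, 217 and 143 cells of tumour 1, tumour 2 and normal, which were divided differently at resolution 2.0: cluster 22 held 15, 68 and 142 of them and cluster 33 held 59, 149 and 1. Mural markers in the class moved both ways. Rgs5 stood at 532, 930 and 4551 CPM and Vtn at 329.8, 452 and 622, whereas Higd1b stood at 474, 426 and 59.5, Acta2 at 94.2, 171 and 2.16, and Kcnj8 at 154, 215 and 96.2.

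Mmp10 (at least 70.4-fold), Esm1 (65.7-fold) and Gpx3 (39.8-fold) also rose from 0 counts in endothelial-like cells, and Cdr1os (-4.48), Sgpp2 (-4.35), Slc6a20a (-4.19) and Rsad2 (-4.07) fell. Of 12 angiogenic genes 9 rose, including Apln (5.60) and Vwf (3.79), and 0 fell (9 adjusted over the list alone; median 2.87, or 2.56 with members at their bound, camera adjusted p = 3.61e-13). Of 12 matrix genes 11 rose, including Lamb1 (5.36) and Bgn (4.02), and 0 fell (11 adjusted over the list alone; median 2.87, or 2.66, adjusted p = 8.04e-12). All 13 mesenchymal genes rose, including Lgals1 (7.28) and Vim (3.02) (13 adjusted over the list alone; median 3.80, or 3.22, adjusted p = 1.35e-14). Of 12 barrier genes 10 fell, including Ocln (-2.82) and Abcb1a (-2.32), and 1 rose (11 and 1 adjusted over the list alone; median -1.61, adjusted p = 1.37e-11). Of 19 interferon genes 13 fell, including Ifit3 (-3.52), Iigp1 (-3.31) and Gbp2 (-3.25), and 0 rose (16 adjusted over the list alone; median -2.33, adjusted p = 2.74e-13). Of 11 MHC class I genes 4 fell, including H2-T23 (-2.27) and B2m (-1.08), and 0 rose (4 lower and 2 higher adjusted over the list alone; median -0.43, adjusted p = 0.0321). Without tumour 2, Sgpp2 changed by -5.04, Ifit3 by -4.86, Iigp1 by -4.11 and H2-T23 by -3.04. With an estimated correlation the adjusted p = 0.626 for these lists, except MHC class I at 0.659.

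Hypoxia genes rose in 8 of 12 cases in endothelial-like cells, including Adm (4.40), and fell in 3, including Ndrg1 (-2.60) (the same counts adjusted over the list alone; median 1.96, camera adjusted p = 0.0245), and chemokines rose in 9 of 11 cases and 0 fell, 4 of them above free RNA (11 adjusted over the list alone; median 7.98, or 2.47 with members at their bound, adjusted p = 1.06e-05). Cell cycle genes rose too: 14 of 15 G2 and M phase genes with 0 above free RNA (15 adjusted over the list alone) and 6 of 14 S phase genes, including Tyms (2.35) and Mcm6 (1.42), with 4 above it (6), while 0 fell (adjusted p = 1.06e-05 and 0.0301, and adjusted p = 0.659 and 0.706 with an estimated correlation). Of genes of other cell types, 16 of 19 disease-associated microglia genes rose with 1 above free RNA (16 adjusted over the list alone) and 9 of 11 progenitor genes with 0 above it (9), while Dll1 of the progenitor list fell (-3.25) above it, or by 1.95 on the log2 scale without tumour 2. Dissociation stress genes, a sign of handling, rose in 7 of 14 cases, including Junb (3.65) and Egr1 (4.14), and fell in 3, including Dusp1 (-1.12), 4 and 3 of them above free RNA (8 and 3 adjusted over the list alone; median 0.92, adjusted p = 0.0364). Astrocyte genes fell in 7 of 11 cases and 0 rose, all 7 above free RNA (7 adjusted over the list alone; median -1.45, adjusted p = 0.00155). The free RNA bound used no astrocyte genes, so it cannot exclude astrocyte RNA carried into these cells. With an estimated correlation the adjusted p = 0.626 for the hypoxia, chemokine, astrocyte and stress lists. The change of interferon genes was higher in microglia-like than in endothelial-like cells by a median of 3.38 (18 of 19 higher, adjusted p = 2.72e-15), and that of MHC class I genes by 1.44 (6 of 12 higher, adjusted p = 8.37e-09). With an estimated correlation the adjusted p = 0.148 for both, and this pair of classes and lists was chosen after their changes had been seen.

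**Figure D4:**
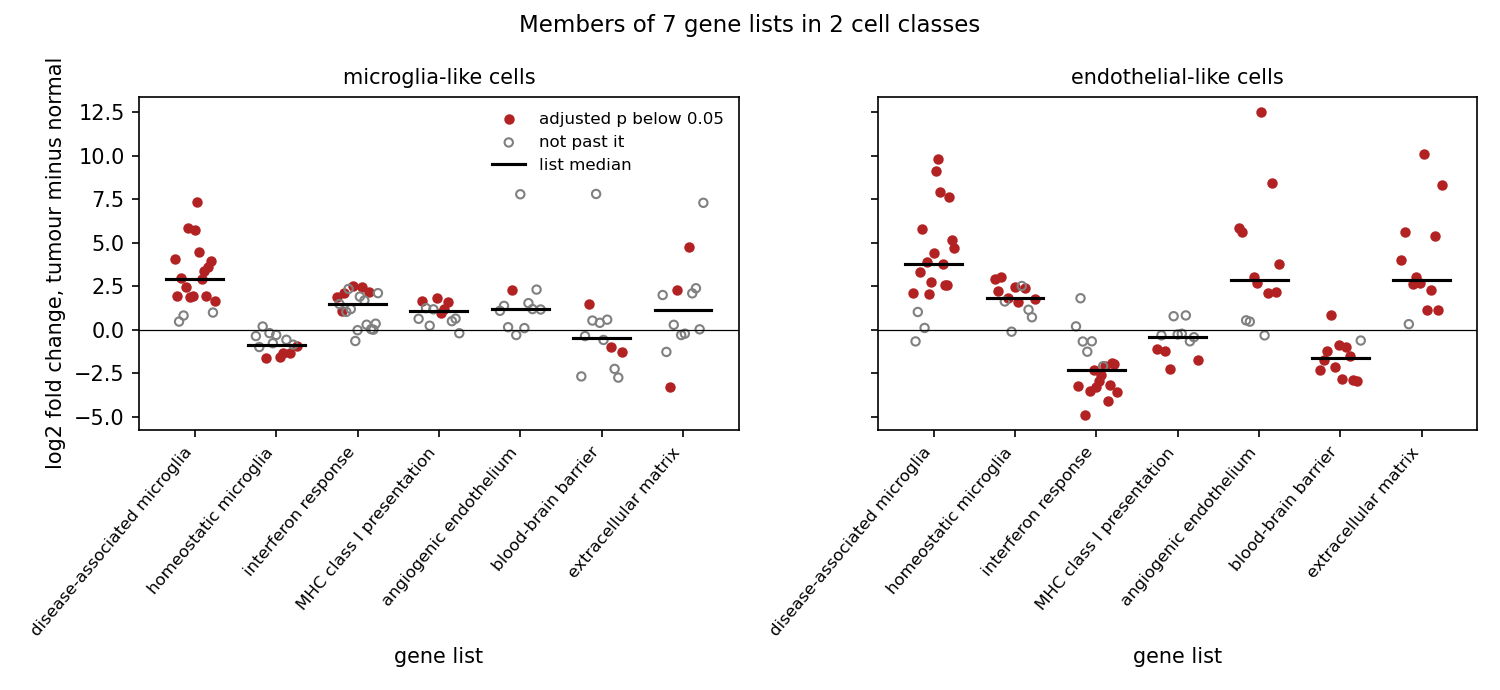
Log2 fold change, tumour minus normal (axis), of the members of 7 gene lists in microglia-like (left) and endothelial-like cells (right), with 1 point per gene (filled where the adjusted p was below 0.05, open otherwise) and a line at each list's median. Interferon genes have a median of 1.48 in microglia-like and -2.33 in endothelial-like cells.

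In macrophage-like cells, with 28 in the normal library, 185 genes rose and 98 fell by edgeR among 12812 tested, and 2106 had an unadjusted p under 0.05. Other scaling ended most of these calls: RLE gave 3 and 14, and library size alone 3 and 56. At resolution 2.0 the class was divided differently between the groups, so its changes can mix kinds of cells. The cluster with 22 of the normal cells held 334 and 797 of tumour 1 and tumour 2. One named monocyte or macrophage held 40, 368 and 3 in tumour 1, tumour 2 and normal. Clusters with 94 and 68 and with 154 and 132 tumour cells held 0 normal ones. Lyve1, a receptor of border macrophages, stood at 6.72 ± 1.95 CPM (SD, n = 2) against 664 (log2 change -5.98, adjusted p = 2.58e-05, edgeR), and the interferon-induced GTPase Iigp1 fell (-7.32, adjusted p = 0.0029). Pkm, a glycolytic enzyme, rose from 0 counts by at least 15.3-fold, and Gpnmb by at least 8.28-fold. Disease-associated genes rose in 9 of 19 cases and 0 fell (11 adjusted over the list alone; median 1.96, camera adjusted p = 5.22e-18), and interferon genes fell in 3 of 19 and 0 rose (8 adjusted over the list alone; median -1.33, adjusted p = 2.52e-15); the adjusted p = 0.952 with an estimated correlation for both. The median log2 change of all genes was 0.94, or 0.32 with library size alone, so changes in this class are relative to an upward shift, and 0 genes passed by edgeR with sums thinned to equal depth (441 at an unadjusted p under 0.05).

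Neutrophil-like cells had 531 genes higher and 619 lower among 9778, of which 252 and 613 lay above free RNA; library size alone gave 1643 and 308. A cluster led by Cxcl2 and Il1r2 held 88.2%, 93.3% and 23.9% of the class in tumour 1, tumour 2 and normal, and one led by Ltf, Ngp and Camp, genes of immature neutrophils, 11.8%, 6.67% and 76.1%. Fcnb fell (-3.99) and Hilpda, at 96.4 and 30.9 CPM in tumour, rose from 0 counts by at least 48.9-fold, or 23.7-fold without tumour 1. Chemokines rose in 8 of 10 cases and 0 fell, 5 above free RNA (9 adjusted over the list alone; median 5.83, or 3.57 with members at their bound, camera adjusted p = 2.23e-11), and G2 and M phase genes fell in 13 of 15 and 0 rose (15 adjusted over the list alone; median -2.32, adjusted p = 1.8e-16). Interferon genes fell in 5 of 17 cases and 0 rose (6 adjusted over the list alone; median -1.20, adjusted p = 0.000327). Dissociation stress genes rose in 10 of 15 cases and 0 fell, 9 above free RNA (14 adjusted over the list alone; median 3.56, adjusted p = 4.51e-15). These 4 lists had adjusted p = 0.480 with an estimated correlation.

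Dendritic-like cells had 432 genes higher and 276 lower among 6838, and library size alone gave 369 and 902. Sums thinned to equal depth gave 424 and 290 after a binomial draw, and 0 and 0 with thinCounts by edgeR (92 at an unadjusted p under 0.05). All 7 MHC class II genes rose and lay above free RNA (7 adjusted over the list alone; median 2.15, camera adjusted p = 2.63e-13, and adjusted p = 0.802 with an estimated correlation), Ccl17, at 635 and 250 CPM in tumour, rose from 0 counts by at least 27.9-fold, or 15.7-fold without tumour 1, and Cox6a2 fell (-6.64, adjusted p = 9.03e-06, edgeR), with 0 and 6.00 CPM in tumour 1 and tumour 2 against 729. Dissociation stress genes rose in 5 of 12 cases and 0 fell, all 5 above free RNA (10 adjusted over the list alone; median 2.67, or 2.05 with members at their bound, adjusted p = 1.31e-06). G2 and M phase genes fell in 10 of 15 cases and 0 rose (14 adjusted over the list alone; median -2.26, adjusted p = 2.14e-13), and mitochondrial genes in 3 of 8 and 0 rose (4 adjusted over the list alone; median -0.56, adjusted p = 0.0191); all of these falls lay above free RNA, and these 3 lists had adjusted p = 0.802 with an estimated correlation. At resolution 2.0 the cells of this class were divided differently between the groups: one cluster held 39, 368 and 8 of them in tumour 1, tumour 2 and normal and kept the name, and an unnamed one held 0, 17 and 34. B-like cells had 272 genes higher and 334 lower among 6135, of which 157 and 327 lay above free RNA, and binomially thinned sums gave 103 and 91. Rag1, the recombinase of B cell precursors, was at 0 counts in tumour and at least 52.8-fold lower, Vpreb1 at least 48.6-fold and Dntt at least 27.1-fold lower, or 7.27-fold, 6.68-fold and 3.73-fold without tumour 2, while 7 of 7 MHC class II genes rose (7 adjusted over the list alone; median 2.97, adjusted p = 1.59e-11) and 15 of 15 G2 and M phase genes fell (15 adjusted over the list alone; median -5.02, or -4.28 with members at their bound, adjusted p = 1.3e-17). The adjusted p = 0.503 with an estimated correlation for both lists. In normal B-like cells Rag1, Vpreb1 and Dntt stood at 426, 391 and 219 CPM. The class thus held B cell precursors in the normal library, and its changes can mix kinds of cells. Of the class II genes 6 lay above free RNA, whose share used in B-like cells of tumour 1 was 93.6%. Disease-associated microglia genes also rose there in 9 of 12 cases and homeostatic ones in 4 of 11, with 0 above free RNA. T or NK-like cells had 219 genes higher and 135 lower, 89 and 121 above free RNA, or 122 and 76 with binomially thinned sums and 14 and 20 after thinCounts, with Ccl1 lower (-7.57, adjusted p = 1.09e-62), at 0 and 5.45 CPM in tumour 1 and tumour 2 against 899.6. Their G2 and M phase genes fell in 8 of 10 cases and 0 rose (9 adjusted over the list alone; median -3.94, adjusted p = 2.49e-24, and adjusted p = 0.688 with an estimated correlation). The normal library held 38 such cells. Thinned to 1000 UMIs, 2 of 79, 4 of 175 and 4 of 35 were cycling in tumour 1, tumour 2 and normal. The exact interval in normal was 3.20 to 26.7%, so the fall rests on few normal cells. All 8 falls lay above free RNA, but the neutrophil genes Ngp and Camp stood at 1541 and 1666 CPM in these normal cells. Whether admixed neutrophil-type cells added to the fall was not tested.

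Astrocyte-like cells had 357 genes higher and 280 lower among 9879, 197 and 261 above free RNA. Sums thinned to equal depth gave 11 and 22 after a binomial draw and 0 and 0 after thinCounts by edgeR (652 at an unadjusted p under 0.05). Slc24a4 rose (log2 change 3.23, or 2.61 without tumour 1, adjusted p = 8.70e-10, edgeR), the adenylyl cyclase gene Adcy1 fell (-5.09, adjusted p = 5.67e-13), and cholesterol synthesis genes fell in 4 of 14 cases and 0 rose (9 adjusted over the list alone; median -0.68, camera adjusted p = 5.17e-07; adjusted p = 0.737 with an estimated correlation). Neuron-like cells had 387 genes higher and 112 lower, of which 46 and 105 lay above free RNA; library size alone gave 0 and 0 by edgeR (983 at an unadjusted p under 0.05) and DESeq2 124 and 5. Choroid plexus-like cells had 15 higher and 34 lower among 2726, 9 and 29 above free RNA, or 0 and 4 with binomially thinned sums (123 at an unadjusted p under 0.05), with Gpx3 lower (-4.10, adjusted p = 4.54e-21). The 5 highest genes in neuron-like cells (Xist, Pdgfra, Hmox1, Ftl1 and Igfbp2) and in T or NK-like cells (Ly86, Trem2, Grn, Hmox1 and Aif1) lay within the level of free RNA. Dissociation stress genes rose in 2 of 10 cases in B-like cells (3 adjusted over the list alone; median 2.50, camera adjusted p = 2.17e-06), in 2 of 9 in astrocyte-like cells (3 adjusted over the list alone; median 0.93, adjusted p = 0.015) and in 1 of 11 in neuron-like cells (1 adjusted over the list alone; median 0.75, adjusted p = 0.0164), and 0 fell. They rose in 3 of 9 and fell in 1 in T or NK-like cells (the same counts adjusted over the list alone; median 0.86, adjusted p = 0.083), and 0 of 15 passed by edgeR in macrophage-like cells (4 at an unadjusted p under 0.05, and 0 adjusted over the list alone; median 1.18, adjusted p = 0.181). With an estimated correlation these lists had adjusted p = 0.503, 0.737, 0.779, 0.688 and 0.952 in turn. Of the stress genes that rose, 2 in B-like, 0 in astrocyte-like, 0 in neuron-like and 1 in T or NK-like cells lay above free RNA.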

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

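Chosen only after the results were seen were the tests on bone marrow genes, on mural UMI share, on a single normal animal and on the microglia and endothelial difference. Of the rest, the test on progenitor genes in neuron-like cells was set before its value was computed, though Xist and Pdgfra levels there had been seen. The endothelial interferon test against free RNA was set before its value was computed.

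Granulocyte precursors, which entered the whole-library sums but had no comparison of their own, made up 7.77% of kept cells in the normal library, against 0.104% and 0.415% in tumour 1 and tumour 2, and genes of marrow lineages were higher there. Dilution by tumour cells was argued against, since among cells outside the progenitor-like class the share in the normal library was still 14.6 times that of the higher tumour library, or 13.8 times with unnamed clusters 5 and 12, of open lineage, left out too. Blood left after perfusion was argued against for the precursor genes only: Rag1, Dntt, Vpreb1 and Elane, which circulating cells do not carry, gave 3317 counts in the normal library. Of these counts 2742 were of Elane, which led the cluster already seen, so the outcome was largely known beforehand. The test cannot tell whether blood added neutrophil-like, B-like or erythroid-like cells. Of 12 further marrow and bone genes, picked as relatives of genes already seen, 12 were over 4 times higher in the normal library than in either tumour library, and 1 of them (Epx) was expressed in a class of normal brain cells. Marrow or bone carried in with the normal tissue is a candidate source, and no biological explanation was tested.

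Median log2 changes of interferon genes were 1.48 in microglia-like and -2.33 in endothelial-like cells, with a median difference of 3.38 (18 of 19 members past the threshold), and that of MHC class I genes was 1.44 (6 of 12); the pair was chosen from 10 tested classes and 27 lists, and neither difference passes with an estimated correlation (adjusted p = 0.148). Free RNA in the normal library was argued against, as interferon genes in normal endothelial-like cells stood at a median of 66.9 times the level it could give (range 1.28 to 212 over 19 genes). Mural cells were argued against as the whole cause: in endothelial-like cells with a low share of mural UMIs the median interferon change was -3.06. A test set beforehand, on cells with no mural UMI, was void with 3 normal cells, and the test by share replaced it. An interferon response in the single normal animal (number of normal samples 1) may account for the difference and stays open, as does an effect of the tumour.

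Genes of glial progenitors rose in 5 of 9 cases in neuron-like, 8 of 8 in neutrophil-like, 9 of 11 in endothelial-like and 7 of 13 in microglia-like cells, such as Pdgfra at 102 and 57.3 CPM in neuron-like cells of tumour libraries against 1.73 in normal. By edgeR 0 of 10 passed in macrophage-like (0 at an unadjusted p under 0.05) and 0 of 6 in dendritic-like cells (1). Free RNA from tumour cells would keep 1 ratio among such genes. The ratio of 7 progenitor genes to their whole-library level differed by at most 2.55 times among them in neuron-like cells of either tumour library, which is consistent with free RNA as the source. No biological explanation was tested.

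In an unnamed cluster led by Tsix and Xist, which likewise had no comparison of its own, Xist stood at 6192 CPM in tumour 1 and 6068 in tumour 2, with 0 cells of the cluster in the normal library.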

How the results depend on the processing

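Chosen after seeing the data were library size scaling, both kinds of thinned sums, the free RNA guard, the whole library without marrow-type clusters and the endothelial-like cells with few mural UMIs; the others were set beforehand. No paired analysis was possible with 1 normal library, which the labels link to neither tumour library. A residual degree of freedom of 1, a single normal library and far fewer UMIs in it limit each count of calls, and small classes most. Over 135 named gene results, alternatives gave 1478 values with the same direction and, where there was a test, the same call, apart from Cd274 in the whole library, which did not pass and changed sign in 2 of them. Of the 1478, 115 without tumour 1 and 86 without tumour 2 had no test and so no call. For genes picked by the naming rule their direction was fixed beforehand, as the rule required the same direction in both tumour mice. A further 177 lost the call, 7 gained one and 69 moved without a test. Results whose gene or class an alternative no longer tested are left out of these counts, not counted as lost. The stricter cell filter, for example, left 62 the same and 3 that gained a call. For the 51 medians of lists past the threshold in the whole library, microglia-like and endothelial-like cells, 203 values kept their direction and 1 reversed. Lists that did not pass are not counted there, and several of their medians changed sign with another scaling or without 1 tumour library: in the whole library those of S phase, MHC class I and II, homeostatic microglia, checkpoint, astrocyte, reactive astrocyte and mesenchymal genes, in endothelial-like cells those of myelin and cholesterol synthesis genes, and in microglia-like cells that of checkpoint genes. Where a count or share differs below, the cause was not tested, except that a guard or a smaller set of cells or counts removes calls by construction.

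Pairs of counts are genes higher and lower in tumour, and a count left out lay within 1.5 times of the reported count. With limma-voom the counts were 589 and 792 in the whole library, 558 and 361 in microglia-like, 112 and 266 in neutrophil-like, 609 and 602 in B-like and 208 and 429 in dendritic-like cells. It gave 0 and 6 in macrophage-like cells (714 at an unadjusted p under 0.05), and 143 higher in astrocyte-like, 1218 in endothelial-like, 40 in T or NK-like and 0 in choroid plexus-like cells (151 at an unadjusted p under 0.05). With DESeq2 they were 44 and 26 in astrocyte-like, 65 and 43 in B-like, 0 and 2 in choroid plexus-like (48 at an unadjusted p under 0.05), 173 and 83 in dendritic-like, 1272 and 683 in endothelial-like, 124 and 5 in neuron-like, 330 and 293 in neutrophil-like and 47 and 23 in T or NK-like cells. DESeq2 also gave 191 lower in macrophage-like and 694 lower in microglia-like cells. With RLE scaling macrophage-like cells had 3 and 14.

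With library size only, counts were 1671 and 3765 in the whole library, 1319 and 3616 in microglia-like, 1643 and 308 in neutrophil-like, 3 and 56 in macrophage-like, 4 and 11 in choroid plexus-like and 0 and 0 in neuron-like cells (983 at an unadjusted p under 0.05 by edgeR). It gave 902 lower in dendritic-like and 142 higher in T or NK-like cells, and turned the p53 target median in microglia-like cells from 0.51 to -0.059. Without a filter on low counts, 120 were higher in B-like and 11 lower in choroid plexus-like cells, with 981 and 959 in neutrophil-like and 0 and 0 in macrophage-like cells (1456 at an unadjusted p under 0.05).

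Sums thinned binomially gave 11 and 22 in astrocyte-like, 103 and 91 in B-like, 0 and 4 in choroid plexus-like, 122 and 76 in T or NK-like and 0 and 0 in macrophage-like cells (123 choroid plexus and 441 macrophage genes at an unadjusted p under 0.05), with 64 lower in neuron-like and 826 higher in neutrophil-like cells. Sums thinned with thinCounts gave 392 and 255 in the whole library, 674 and 379 in endothelial-like, 114 and 38 in B-like and 14 and 20 in T or NK-like cells, with 848 higher in neutrophil-like cells. It gave 0 and 0 in astrocyte-like (652 at an unadjusted p under 0.05), choroid plexus-like (21), dendritic-like (92), macrophage-like (97) and microglia-like cells (530), all by edgeR. Genes above free RNA numbered 197 higher in astrocyte-like, 157 in B-like, 9 in choroid plexus-like, 46 in neuron-like, 252 in neutrophil-like and 89 in T or NK-like cells.

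With a stricter cell filter, counts were 4271 and 3475 in the whole library and 1188 and 506 in microglia-like cells, and the log2 change of cell numbers was 4.84 for macrophage-like and -3.45 for neuron-like cells, both past the threshold (adjusted p = 0.0482, edgeR). With no cell filter they were 991 and 1784 in astrocyte-like, 23 and 75 in choroid plexus-like, 226 and 618 in neuron-like and 990 and 1031 in neutrophil-like cells, with 442 higher in B-like cells. With doublets kept they were 1285 and 731 in astrocyte-like, 66 and 59 in macrophage-like and 783 and 260 in neuron-like cells, with 420 higher in B-like cells, and cell numbers of progenitor-like (9.92) and oligodendrocyte-like cells (-5.17) no longer passed (adjusted p = 0.103 for both, edgeR). Resolution 2.0 gave 333 and 168 in macrophage-like cells, 428 higher in B-like, 339 lower in neutrophil-like and 121 higher in T or NK-like cells, and resolution 0.5 gave 0 and 2 in choroid plexus-like cells (286 at an unadjusted p under 0.05). Endothelial-like cells with few mural UMIs gave 1320 and 765. Leaving out each tumour library, cell numbers changed by -5.27 to -2.84 in B-like and -1.88 to 1.58 in dendritic-like cells, with no test.

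Camera with an estimated correlation and fry each left 0 lists past the threshold in the 11 comparisons, where the preset correlation gave 17 of 27 in the whole library, 17 of 26 in microglia-like and 17 of 26 in endothelial-like cells. At an unadjusted p under 0.05, the estimated correlation gave 0 lists in each comparison and fry 5, 5 and 6 lists in those 3. With 1 residual degree of freedom the estimated correlation had almost no power, so its 0 lists decide nothing either way. Cycling shares moved with depth. Thinned to 2000 UMIs they were 25.9% and 30.6% in progenitor-like cells of tumour 1 and tumour 2 and 12.0%, 10.5% and 2.30% in microglia-like cells of tumour 1, tumour 2 and normal. Unthinned they were 53.4% and 60.7%, then 20.0%, 20.2% and 1.78%, with 9.41% in neuron-like cells of tumour 1. With 6 cell cycle genes they were 24.3% and 29.0% in progenitor-like cells of tumour 1 and tumour 2. In tumour 1, tumour 2 and normal they were then 14.0%, 10.7% and 1.04% in microglia-like, 8.43%, 10.2% and 4.12% in neuron-like and 5.08%, 18.3% and 0.709% in endothelial-like cells. With doublets kept they were 1.04% in normal microglia-like cells and 5.0% in endothelial-like cells of tumour 1. With the stricter cell filter they were 25.5% and 33.1% in progenitor-like cells and 1.96% in normal microglia-like cells.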

Other observations

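The tests on sex-linked genes and on chromosomes were chosen only after the result was seen. Mural-like cells, which had 4 cells in the normal library and no gene test, carried Cdkn2a at 517 and 348 CPM in tumour 1 and tumour 2, beside 438 and 457 in progenitor-like and 137 and 77.6 in endothelial-like cells. Pdgfra in mural-like cells stood at 177 and 56.6 CPM, beside 1174 and 1055 in progenitor-like cells. The highest free RNA share found in mural-like cells was 171% of the whole-library level in tumour 1 and 33.6% in tumour 2. That of tumour 1 came from neutrophil genes ranging from 0 to 1167%, so it gives no usable bound. The 7 progenitor genes gave medians of 20.6% and 11.5% in tumour 1 and tumour 2. Pdgfra is 1 of them, and its values lie within that level. Cdkn2a stood above its whole-library levels of 328 and 223 CPM in both, more than these progenitor shares give. Its source there was not tested. The gene of the checkpoint ligand PD-L1, Cd274, stood at 0.628, 2.78 and 17.3 CPM in endothelial-like cells of tumour 1, tumour 2 and normal.

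A hypothesis is that the glial progenitor-like cells come from the injected line and that its sex differs from that of the hosts. Their summed Y gene level was at most 0.0249 times that of microglia-like cells of the same library, which is consistent with a line without a Y chromosome or without its expression. The sex of the line and of the mice was not used here as a label.

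A further hypothesis is that unnamed cluster 12, led by Tsix and Xist, belongs to the same lineage. Against normal astrocyte-like cells, median log2 expression of genes on chromosomes 12 and 18 was -0.83 and -0.71 in progenitor-like cells of tumour 1 and -0.72 and -0.75 in tumour 2, and chromosome 15 stood at 0.43 and 0.45. In unnamed cluster 12 these chromosome 12 and 18 medians were -0.53 or lower in both tumour libraries, which may point to a shared lineage. For unnamed cluster 5, led by Gap43 and Fabp7, they were -0.47 or lower, but its Xist level was 178 and 202 CPM in tumour 1 and tumour 2, far below the 1072 and 1059 of progenitor-like cells, and 17 of its cells came from the normal library. Its summed Y gene level of 18.2 and 16.6 CPM goes the other way, being far below the 201 and 181 of microglia-like cells, so its lineage stays open; in cluster 12 the Y level was 10.7 and 53.02 CPM. Whether these shifts reflect copy number or cell type cannot be told apart. Among 38 other groups of cells the largest shift was 0.35, on chromosome 4 of neutrophil-like cells in tumour 2, and the bound for this test was made stricter after that value had been seen.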
